A study of Homo sapiens with 23 samples.

How the data were processed

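Single-cell RNA counts were available for 23 libraries from 7 donors with hepatocellular carcinoma (HCC, the main primary cancer of the liver). Per the labels' protocols, innate lymphoid cells (ILCs, lymphocytes that carry no rearranged antigen receptor) were enriched by flow sorting from freshly isolated cells and loaded on the BD Rhapsody platform, which pairs single cells with barcoded beads in microwells. Per the labels' protocols, libraries were then made with a targeted primer panel. Of these targeted libraries there were 22 from 6 donors: 6 of tumor, 5 of the tumor margin, 6 of non-tumor liver and 5 of PBMC (peripheral blood mononuclear cells). The labels give Liver as the source name of the PBMC libraries, while their title and cell type say PBMC. These libraries were treated as blood. Donors carry the letters A to G here. The remaining library is a tumor library of donor G made with 10x Genomics droplets, for which the labels describe no separate protocol. The labels name the sort only as enriching ILC populations, so the gates that let in other cells are unknown.

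Values in the deposited tables of 21 targeted libraries are counts of molecules per cell and amplicon after the pipeline's correction of molecular indices, without normalization, per the file headers and names. Non-tumor library A was deposited as counts of reads per cell, which are on another scale, and it was left out of the main tests. Per the file headers, the BD Targeted Rhapsody Analysis Pipeline made the tables, in version 1.02 for 3 of the molecule libraries (tumor A, margin A and margin B) and in version 1.3 for the other 18. The submitters' processing notes name bcl2fastq 2.17, Bowtie2 without a version and the build hg38. The deposited 10x matrix holds counts of molecules per gene and barcode from cellranger 5.0.1, per the file header. The panel columns name a gene symbol and a transcript for each of 405 amplicons and give no coordinates. Amplicons of the same gene or transcript form were summed, which left 402, of which 12 were immunoglobulin amplicons. The labels mention protein measurements, but the files held 0 antibody tag columns, so the planned test of protein tags was not run.

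The 21 molecule libraries held 27039 cells, of which 27031 had at least 30 molecules and were kept. Counts were scaled to 200 per cell, logged, reduced to 25 principal components without the immunoglobulin amplicons, and clustered with the Leiden method at resolution 0.5 on a graph of 20 nearest neighbours. Clusters were named by fixed marker lists of 12 cell classes: at least 3 markers had to be 1.5 times higher than in the other cells, more than for any other class, with at least 1 marker among the 10 leading genes and no other class holding more of these. Resolution 1 had been planned, but it left the blood cluster of ILC2 type without a name, so 0.5 was chosen after the cluster names were seen and before any share or gene was tested. Of the cells, 24124 fell in named classes. As a check, cells of each library were named by their nearest neighbours in the other libraries. The median share named the same way was 98.8%, with 96.6% in the lowest library. The components, clusters and class names still came from all libraries together. High agreement is therefore built in, and the check does not show that the names would hold without a library. The doublet caller in the style of scrublet marked 71 cells (0.263%), too few for it to have worked, and the alternative without marked doublets, fixed earlier, was replaced by leaving out the 5% of cells with the highest doublet score.

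Cells of 1 library are not independent, so tests used libraries as replicates. Counts were summed over the cells of each library. All 4 groups were fitted together in edgeR 4.0.16 under R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F test, 2-sided), with Benjamini-Hochberg adjustment over all panel genes tested and a threshold of 0.05. The same fit was run within NK-like, ILC2-like and ILC3-like or ILC precursor-like cells, for libraries with at least 20 cells of the class and at least 3 libraries in each arm. T-like cells met this in too few margin and non-tumor libraries, so single genes were not tested within them. Gene lists within class, added later, were also tested in T-like, B-like and myeloid-like cells where both arms had at least 3 libraries. Class shares were compared with exact 2-sided permutation tests of the difference in mean share, adjusted over all classes and comparisons. The smallest p these can give is 0.00216 for 6 against 5 libraries and 0.00794 for 5 against 5. Adjusted over all classes and comparisons, 0.00216 becomes 0.0909 when no other share is as low. A single share therefore cannot pass by itself, however well the groups separate. Levels are CPM, counts scaled to the same total of panel counts in each library, with the SD over libraries, and log2 fold changes carry the standard error of the edgeR fit.

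Of 18 fixed gene lists, 16 had at least 3 measured members and were tested with fry in limma 3.58.1 on voom values, adjusted over lists and comparisons. The lists were cytotoxic effectors (12 of 15 members on the panel), NK receptors (13 of 21), an ILC1 program (10 of 10), an ILC2 program (12 of 17), an ILC3 and ILC precursor program (13 of 17), circulation and naive state (8 of 11), tissue residency (11 of 12), immediate early and stress genes (10 of 17), secreted cytokines and chemokines (24 of 28), checkpoint and co-stimulatory receptors (16 of 21), interferon response (3 of 14), MHC class II (5 of 10), proliferation (9 of 15), T cell markers (13 of 15), B and plasma cell markers (18 of 18, tested as 20 transcript forms, since IGHM and IGHG1 each have a membrane and a secreted form) and myeloid cell markers (14 of 23). The mast cell and basophil markers (4 of 8) and the hepatocyte and stromal markers (0 of 15) were not tested. The fry p asks whether the genes of a list move on balance in one direction and does not compare the list with other genes. Camera, which does, was run with a preset and with an estimated correlation between genes.

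Named genes followed a rule: of the genes past the threshold with at least 50 CPM in the higher group, the 12 with the largest rise and the 12 with the largest fall. Where fewer than 5 genes passed, the 5 with the lowest p were named as not passing. From each list, 2 to 4 members with the lowest p were added. Some genes that these rules pick are not reported here. Where a group had 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts a ratio of summed counts with its exact 95% counting interval replaces the fitted fold. Intervals and floors cover counting error only. The groups, comparisons, tests, lists, markers and naming rule were fixed before the data were examined.

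The same donor letters stand for the donor numbers in the labels, which pair libraries of the same donor. This pairing was checked on the values: of 28 same-donor pairs of libraries, 18 had a correlation over 0.1 after group means were removed, with a median of 0.243 against -0.0638 between donors. The lowest same-donor correlation was -0.278, so not every pair showed the pairing. How many pairs of different donors exceeded 0.1 was not counted. Donor entered only as a replicate block in an alternative. No duplicate libraries were found, since the lowest chi-square per degree of freedom over 45 pairs of libraries of 1 group was 66.7. In the 10x library, cells with at least 200 genes were kept, clustered at resolution 1 and named with the same markers. The doublet caller marked 2 of 3799 cells there, too few for it to have worked, and no cell was left out as a doublet. Sex-linked genes (132) and the segments of antigen receptors were left out of it.

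The tests were tested on simulated data drawn from the observed libraries, with 200 of 398 genes changed in 10 repeats. Over all cells, changes of 2-fold, 4-fold and 16-fold were recovered for 8.51%, 41.5% and 85.8% of genes in tumor against non-tumor, 4.79%, 35.1% and 81.1% in margin against non-tumor, and 8.53%, 39.9% and 84.5% in tumor against margin. Against PBMC these were 8.60%, 38.0% and 82.2% for non-tumor, 8.15%, 40.5% and 84.3% for tumor, and 7.60%, 37.6% and 84.2% for margin. At most 2.64% of calls were false. Within class, non-tumor against PBMC, the shares were 21.1%, 66.2% and 96.9% in NK-like cells, 10.5%, 48.8% and 93.7% in ILC2-like cells, and 12.8%, 61.2% and 97.0% in ILC3-like cells, with at most 3.11% of calls false. A list raised 4-fold was called in 10 of 10 repeats and no list was called without a change. Each gene was drawn independently, without donor effects or shared shifts in class shares. The simulation therefore cannot show how often genes or lists that move together give false calls in the real data. The exact permutation test gave p under the threshold in 4.85% of 4000 draws without a difference.

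Alternatives planned before the data were examined were other scalings, no filter on low counts, DESeq2 1.42.0, the 2 groups alone in the fit, a donor block, no minimum of molecules, at least 50 cells per class and library, other resolutions, only NK-like and ILC-like cells, the reads library added, and each library left out. Chosen after seeing the data were the leaving out of high doublet scores, of immunoglobulin amplicons, of version 1.02 libraries and of the 2 libraries in doubt (tumor A and margin E), shares among NK-like and ILC-like cells alone, and lists within class. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.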

Results

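Cells from a sort for ILCs were profiled in people with HCC at 4 sites: the tumor, its margin, non-tumor liver and blood (PBMC). The series asks how the surroundings of a tumor shape ILCs and related cells, so tissue sites were compared with each other and with blood. Molecule counts were available for 6 tumor, 5 margin, 5 non-tumor and 5 PBMC libraries of donors A to F. The libraries held 233 to 7452 cells. Total counts were 69524 to 1218860 per tumor library, 166522 to 1325811 per margin library, 168217 to 2122614 per non-tumor library and 203152 to 496476 per PBMC library. The median of molecules per cell was 111 to 255 in tumor, 203.5 to 252 in margin, 231 to 290 in non-tumor and 179.5 to 342 in PBMC libraries. Immunoglobulin amplicons took 1.46% to 94.6% of a library's counts, the most in margin E. A value per group with ± is a mean over libraries, with the SD over libraries and their number.

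The sort let through natural killer cells (NK, cytotoxic lymphocytes), ILC2-type and ILC3-type cells, and also B, plasma, T and myeloid cells. Clusters 1, 2, 5 and 13 of 20 were NK-like, clusters 3 and 14 were ILC3-like or ILC precursor-like, and clusters 7 and 9 were ILC2-like. No cluster met the rule for ILC1. Cluster 5, led by the ILC1 marker CXCR3, was named NK-like by 3 raised markers against 2 for the next class. Non-tumor and PBMC cells of most classes fell into separate clusters. The percents of a class given next are means over libraries with at least 20 of its cells. Cluster 9 held 98% of non-tumor ILC2-like cells and cluster 7 held 99.5% of those of PBMC. Of tumor ILC2-like cells 784 lay in cluster 7, most of them from tumor D, and 569 in cluster 9. Cluster 3 held 99.4% of non-tumor ILC3-like cells and cluster 14 held 99.4% of those of PBMC. Of NK-like cells, cluster 1 held 55.2% ± 28.6 (SD) in non-tumor liver, cluster 5 held 48.8% ± 42.1 in tumor and cluster 13 held 66.8% ± 32.3 in PBMC. Cluster 2 held 17.1% ± 20.8 in non-tumor liver and 31.1% ± 33.8 in PBMC. With cells pooled, cluster 2 held 3882 of 8862 NK-like cells of non-tumor liver, and non-tumor B supplied 83.6% of that cluster. T-like cells lay in cluster 8 in non-tumor liver (97.4%) and in cluster 15 in PBMC (94.1%), and B-like cells in cluster 11 in non-tumor liver (87.8%) and mainly in cluster 6 in PBMC (81.5%). Cluster 4, with 2560 cells and no name, came to 94.3% from tumor library A.

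**Figure D1:**
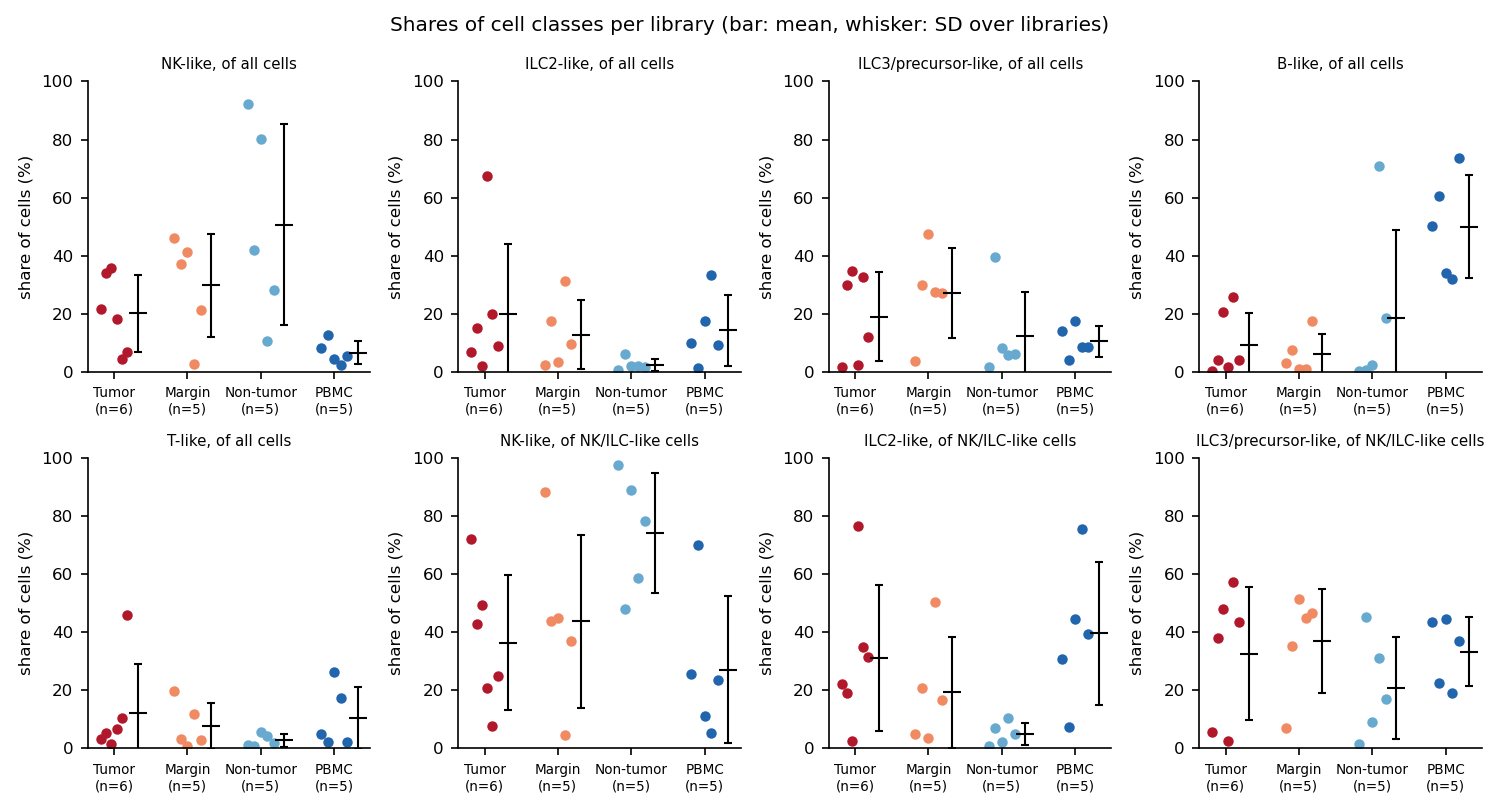
Share of cells (percent) per library by site for 5 classes among all cells and for 3 classes among NK-like and ILC-like cells alone; points are libraries, bars are means and whiskers are SDs. The mean NK-like share of all cells was 20.2% in tumor and 50.6% in non-tumor liver, with overlapping libraries.

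Tumor and non-tumor liver were compared to ask which cells and genes differ inside the tumor. Tumor libraries held on average fewer NK-like cells and more ILC2-like cells than non-tumor libraries, but donors varied widely and no share passed adjustment. No single panel gene passed either. The list of NK receptors passed as lower in tumor over all cells, but not with an estimated correlation (adjusted p = 0.381). None of its members passed alone, 34 of 100 splits of the libraries gave as many list calls, and the list did not pass inside NK-like cells.

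In libraries from the ILC sort, the NK-like share of all cells was 20.2% ± 13.2 (SD, n = 6) in tumor and 50.6% ± 34.6 (n = 5) in non-tumor liver. The exact permutation p was 0.0801 and the adjusted p 0.333. Within the 5 donors with both sites the share was lower in tumor in 5 of 5. The ILC2-like share was 19.9% ± 24.1 (n = 6) against 2.43% ± 2.09 (n = 5), with an exact permutation p of 0.0476 and an adjusted p of 0.295, and was higher in tumor in 4 of 5 donors. Its tumor median was 11.9%, and without tumor D the mean was 10.4%. ILC3-like or precursor-like cells made up 18.9% ± 15.4 and 12.2% ± 15.4. Among NK-like and ILC-like cells alone, a denominator chosen after seeing the data, the NK-like share was 36.3% ± 23.2 in tumor and 74.3% ± 20.7 in non-tumor liver (exact permutation p 0.0260, adjusted p 0.117), and lower in tumor in 4 of 5 donors. On the same base the ILC2-like share was 31.1% ± 25.0 and 4.97% ± 3.86 (exact permutation p 0.0238, adjusted p 0.117).

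Over all cells, 0 of 340 genes passed in edgeR for tumor against non-tumor, with 44 at an unadjusted p under 0.05, and 0 passed in DESeq2, with 50 unadjusted. The 5 genes with the lowest p, none of which passed (adjusted p 0.296), were CHI3L1, IL12RB2, DPP4, CCR2 and ZNF683. CHI3L1, a secreted glycoprotein, had 17446 counts in tumor and 2 in non-tumor liver, a ratio of 12560 (95% counting interval 3476 to 103717), and it is a leading gene of cluster 4, which came mostly from tumor A. The chain of the interleukin 12 receptor IL12RB2 had a log2 fold change of -1.97 ± 0.61 (SE), with 0 of 6 tumor libraries above the non-tumor mean. DPP4, CCR2 and ZNF683, which are among the leading genes of the ILC2-like cluster 7, had log2 fold changes of 2.62 ± 0.81, 3.46 ± 1.09 and 4.50 ± 1.46. Cluster 7 took 58% of its cells from tumor D. Without non-tumor C, DPP4 alone passed, and with a donor replicate block IGHA1_secreted alone did, lower in tumor.

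Of the 16 lists, only the 13 NK receptors passed between tumor and non-tumor liver over all cells (fry, down, adjusted p 0.0224; adjusted p = 0.381 with an estimated correlation). In edgeR 11 of the 13 were lower, with a median log2 fold change of -1.3. None passed alone, also when adjusted over the list alone. Examples were KLRF1 at -2.28 ± 0.85 (567 against 2730 CPM) and CD160 at -2.21 ± 0.78, with 0 of 6 tumor libraries above the non-tumor mean for each. The call was lost without tumor A (adjusted p 0.0622), non-tumor B (0.0849), non-tumor D (0.0560) or tumor F (0.0568). The median voom log2 change, -1.57 with all libraries, was then -1.44, -1.02, -1.59 and -1.43. It was also lost among version 1.3 libraries alone (adjusted p 0.0897), and it held with a donor replicate block (adjusted p 0.0169). Cytotoxic effectors (adjusted p 0.393, lower, with PRF1 at -1.32 ± 0.55 and CST7 at -1.21 ± 0.44) and the ILC2 program (adjusted p 0.116, higher, with IL1RL1 at 2.46 ± 0.89 and PTGDR2 at 3.05 ± 1.22) did not pass, while the ILC2 program did with the replicate block (adjusted p 0.0180). The remaining 13 lists had adjusted p of 0.560 to 0.940. Adjusted over the list alone, 1 gene passed, IL12RB2 in the ILC1 program.

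**Figure D2:**
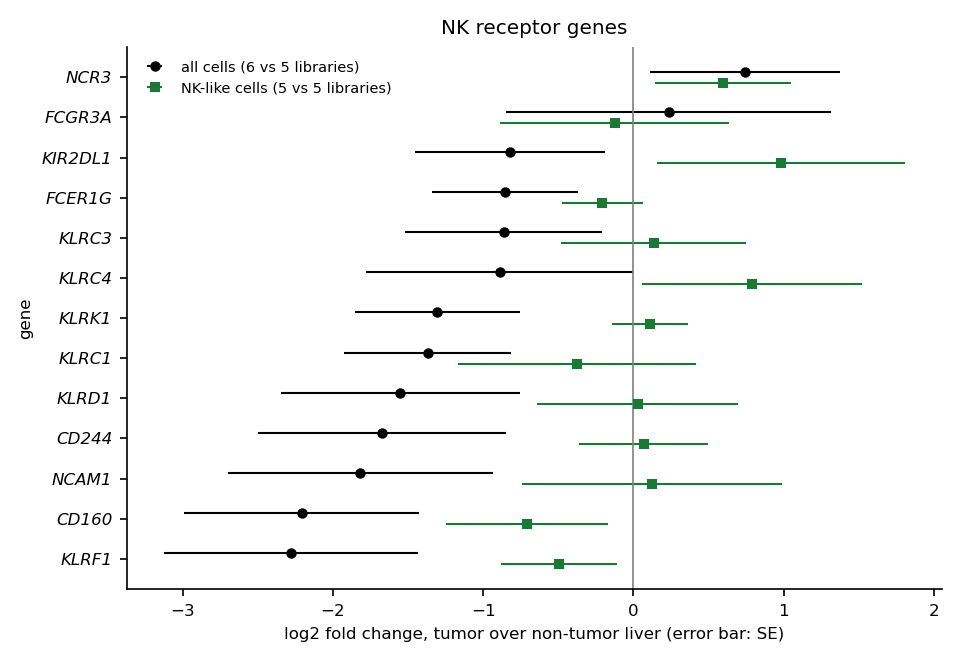
Log2 fold change of 13 NK receptor genes, tumor over non-tumor liver, over all cells (circles, 6 against 5 libraries) and within NK-like cells (squares, 5 against 5 libraries); bars are standard errors and no gene passed alone. Over all cells 11 of 13 genes were lower in tumor, at -2.28 to 0.74, and within NK-like cells 5 of 13 were, at -0.71 to 0.98.

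Within NK-like cells, a test chosen after seeing the data, the NK receptors had an adjusted p of 0.323 (fry, down). Their median was -0.16 in voom with 4 of 13 higher, while edgeR placed 5 of 13 lower, so the sign differed by method, and whether the change differs from that over all cells was not tested. Within classes no gene passed between tumor and non-tumor liver in edgeR or DESeq2. In edgeR, 11 of 196 genes had an unadjusted p under 0.05 in NK-like cells, 5 of 176 in ILC2-like cells and 7 of 190 in ILC3-like or precursor-like cells, and in DESeq2 these were 22, 7 and 9. In NK-like cells the lowest p, with an adjusted p of 0.652, belonged to CCL5 (log2 fold change 0.92 ± 0.29, higher in 5 of 5 libraries), ANXA5 (1.49 ± 0.51), the integrin ITGAE (1.5 ± 0.53), SELPLG (1.48 ± 0.56) and CD247 (-0.92 ± 0.35). CCL5, ITGAE and SELPLG are leading genes of cluster 5, with a mean of 48.8% of NK-like cells in tumor and 20.2% in non-tumor liver. CD247 is a leading gene of cluster 1, with 8.85% and 55.2%. In ILC2-like cells they were CD79B, IRF8, LAT, HLA-DQB1 and LGALS9 (adjusted p 0.865 to 0.911). In ILC3-like or precursor-like cells they were LIF (-1.93 ± 0.61), EGR1 (-2.13 ± 0.75), TNF (-1.43 ± 0.55), FOSB (-1.19 ± 0.50) and CST7 (-1.57 ± 0.68), with an adjusted p of 0.985.

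Margin and non-tumor liver were compared to ask whether changes reach the border of the tumor. Margin libraries lay between tumor and non-tumor liver in their mean NK-like and ILC2-like shares. Without tumor D, however, the ILC2-like mean of tumor was 10.4%, below that of margin. No share, gene or list passed. NK-like cells made up 29.8% ± 17.7 of margin cells (n = 5, exact permutation p 0.278) and ILC2-like cells 12.8% ± 11.9 (n = 5, exact permutation p 0.0556), with a mean of 8.23% without margin E. In edgeR 0 of 340 genes passed, with 15 at an unadjusted p under 0.05, and in DESeq2 0 passed, with 24. The lowest p belonged to CHI3L1 (ratio 2284, 95% counting interval 631 to 18874, adjusted p 0.690), then CD300A (-1.78 ± 0.71), the checkpoint receptor TIGIT (-1.77 ± 0.72), CD160 (-2.03 ± 0.83) and SELPLG (0.91 ± 0.37), with an adjusted p of 0.805. NK receptors had an adjusted p of 0.225 (down), the ILC2 program 0.335 (up) and the other lists 0.657 to 0.924. With the donor replicate block the ILC2 program (adjusted p 0.0397, up) and the ILC3 program (0.0412, up) passed. Camera was not run with the block in any comparison, so these calls have no result at an estimated correlation.

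Within classes 0 genes passed between margin and non-tumor liver in edgeR and DESeq2. Unadjusted, 1 gene in NK-like, 6 in ILC2-like and 6 in ILC3-like or precursor-like cells had p under 0.05 in edgeR, and 1, 5 and 4 in DESeq2. Among the lowest p in NK-like cells were those of IGKC, SELPLG, ITGAE and ANXA5 (adjusted p 0.999), and SELPLG was at 1.15 ± 0.58. SELPLG and ITGAE are leading genes of the NK-like cluster 5. In ILC2-like cells CXCR3 was at -2.62 ± 0.87 (adjusted p 0.969), followed by IGHG1_secreted, IGHG2_secreted, CD79B and IGKC. In ILC3-like or precursor-like cells LIF was at -1.67 ± 0.64, EGR1 at -1.96 ± 0.78, NKG7 at -2.31 ± 0.93 and IKZF2 at -1.28 ± 0.54, and IGHG1_secreted was the other. With 1 library left out NKG7 ran from -2.83 to 0.72, so its direction can turn.

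Tumor and margin were compared to ask what sets the tumor apart from its border. Their class shares differed by less than the spread between libraries, with a lowest exact permutation p of 0.314. No gene or list passed. In edgeR 0 of 340 genes passed, with 11 at an unadjusted p under 0.05, and in DESeq2 0, with 15. The lowest p belonged to CCR2 (2.69 ± 1.05), ZNF683 (3.51 ± 1.39), the plasma cell receptor TNFRSF17 (-3.43 ± 1.43), the lipase LIPA (1.12 ± 0.49) and the mast cell tryptase TPSAB1 (5.59 ± 2.50), all with an adjusted p of 0.991. With 1 library left out ZNF683 ran from -0.33 to 3.78 and TNFRSF17 from -3.93 to 0.19, so both can turn direction. Lists had adjusted p of 0.560 to 0.940. Within classes 0 genes passed, with 4, 5 and 3 unadjusted in NK-like, ILC2-like and ILC3-like or precursor-like cells in edgeR and 6, 5 and 3 in DESeq2. Among the lowest p were those of CD72, IGHG2_secreted, VEGFA (-1.42 ± 0.66) and TCF7 (-1.57 ± 0.75) in NK-like cells. They were LGALS9 (2.41 ± 0.99), CCR2, IGKC, ZNF683 and ITGAM (1.27 ± 0.59) in ILC2-like cells. They were HLA-DRA (1.12 ± 0.46), NT5E (1.11 ± 0.46), CD247 (1.4 ± 0.65), IGKC and CD48 (-0.61 ± 0.31) in ILC3-like or precursor-like cells.

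**Figure D3:**
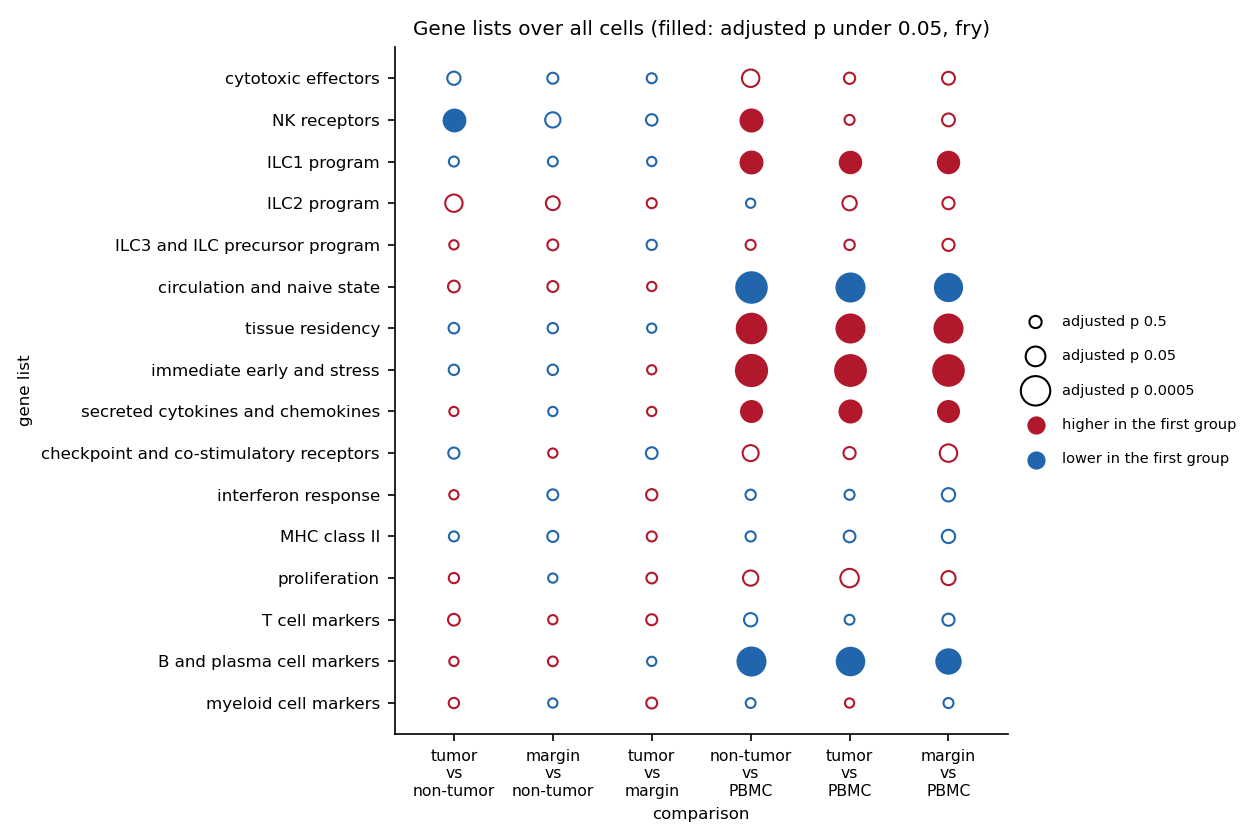
Gene lists (vertical) by comparison (horizontal) over all cells, tested with fry; the circle grows as the adjusted p falls, red is higher and blue lower in the first group, and filled circles passed. Immediate early genes had an adjusted p of 1.86e-04 for non-tumor liver against PBMC, and NK receptors 0.0224 for tumor against non-tumor liver (adjusted p = 0.381 with an estimated correlation for each).

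Non-tumor liver and PBMC were compared to ask how sorted cells of the liver differ from those of blood. Of 340 genes 112 passed, with FOSB, RGS1 and VEGFA among those higher in liver and CX3CR1, TCL1A and CD79B among those higher in blood. B-like cells were on average the largest class of the PBMC libraries. Part of these changes were also called inside NK-like, ILC2-like and ILC3-like cells taken one class at a time.

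NK-like cells made up 50.6% ± 34.6 (n = 5) of sorted non-tumor cells and 6.59% ± 3.93 (n = 5) of sorted PBMC (exact permutation p 0.0159, adjusted p 0.222). ILC2-like cells made up 2.43% ± 2.09 and 14.3% ± 12.1 (exact permutation p 0.0397). B-like cells made up 18.6% ± 30.2 and 50% ± 17.7, T-like cells 2.72% ± 2.15 and 10.5% ± 10.7, and ILC3-like or precursor-like cells 12.2% ± 15.4 and 10.5% ± 5.24. Single libraries decide some of these means: without non-tumor E the B-like mean was 5.55%, without non-tumor C the ILC3-like mean was 5.36%, below that of PBMC, and without PBMC D the T-like mean was 6.60%. The ILC2-like mean was 1.53% without non-tumor C and 9.47% without PBMC E. None passed adjustment.

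Over all cells, 112 of 340 genes passed in edgeR, 74 higher in non-tumor liver and 38 higher in PBMC. DESeq2 gave 133, total counts in place of TMM 54 and the 2 groups alone 67. Genes of B cells fell in liver: TCL1A (-5.59 ± 1.33), CD79B (-4.63 ± 1.01, 173 against 4215 CPM), PAX5 (-4.31 ± 1.23), CD24 (-4.14 ± 1.05), FCER2 (-4.06 ± 1.17) and BLNK (-4.06 ± 1.24), with IGHG1_membrane, IGHM_membrane and VPREB3. A lower B-like share alone does not account for these falls, since they also held in non-tumor E, with 70.8% B-like cells. TCL1A, CD79B and IGHM_membrane lead cluster 6, the main B-like cluster of PBMC. They are not among the leading genes of cluster 11, the main one of non-tumor liver. T cell genes CD3G (-4.18 ± 1.31) and LEF1 (-3.68 ± 0.95) fell, as did FAM65B (-4.12 ± 0.54, 143 against 2472 CPM). The largest rises were in IFNG (8.57 ± 2.04, 4448 against 10.8 CPM), VEGFA (6.53 ± 1.08, 2227 against 22.9 CPM), CCL20 (6.27 ± 1.35), IL1R2 (5.85 ± 1.68), CCL4 (5.82 ± 1.15), C1QA (5.76 ± 2.01) and DUSP4 (5.76 ± 0.88). MMP9 had no count in PBMC and was at least 46-fold higher. Ratios of counts were 115 for CCL22 (31.7 to 950), 63.9 for C1QB (21.8 to 311), 140 for CXCL3 (38.5 to 1156) and 117 for SPP1 (32.2 to 967). Each of the 12 falls held in 5 of 5 libraries, and each rise in 5 of 5 except C1QA, C1QB and SPP1 (4 of 5). With the donor replicate block the call was lost for C1QA (adjusted p 0.0526). Of the 24 genes, 17 kept their call whichever library was left out. The call was lost for CD3G without PBMC D (adjusted p 0.142), for C1QB without PBMC D or non-tumor F (up to 0.0813) and for IGHG1_membrane without non-tumor B or C (up to 0.0659). It was lost for C1QA without PBMC C, D, E or F or non-tumor F (up to 0.252), and for SPP1 without any single PBMC library or non-tumor C (up to 0.134). It was lost for IGHM_membrane (up to 0.0738) and VPREB3 (up to 0.0635) without non-tumor B, C, D or F or PBMC F.

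Of the 16 lists, 7 passed between non-tumor liver and PBMC, and in each the direction of the test, the median and the mean had the same sign. None of the 7 passed with an estimated correlation (adjusted p = 0.381 to 0.786). Immediate early and stress genes rose (adjusted p 1.86e-04; 6 of 10 rose, 6 adjusted over the list alone), with FOSB at 4.29 ± 0.58 (8825 against 449 CPM) and DUSP2 at 3.92 ± 0.61. Tissue residency rose (4.83e-04; 5 of 11 rose, 6 adjusted over the list alone), with RGS1 at 4.77 ± 0.77 and CXCR6 at 5.18 ± 0.74. Circulation genes fell (2.69e-04; 3 of 8 fell, 3 alone), with LEF1 at -3.68 ± 0.95 and CX3CR1 at -3.67 ± 1.09. B and plasma cell markers fell (0.00114; 7 of 20 fell, 7 alone). NK receptors rose (0.0202; 7 of 13 rose, 10 alone), with CD160 at 3.54 ± 0.88 and KLRF1 at 2.79 ± 0.92, where NK-like cells were more frequent. The ILC1 program rose (0.0213; 3 of 10 rose, 5 alone), with IL12RB2 at 4.76 ± 0.74 and STAT4 at 2.63 ± 0.49. Cytokines and chemokines rose (0.0314; 9 of 19 rose, 9 alone), with CSF2 at 4.86 ± 1.13.

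With the estimated correlation the adjusted p was 0.381 for immediate early, residency, circulation and B cell lists, 0.700 for NK receptors, 0.739 for cytokines and 0.786 for the ILC1 program. Leaving out 1 library left 5 to 8 lists, and with the donor replicate block cytotoxic effectors passed too (adjusted p 0.00211, up). The lists that did not pass were cytotoxic effectors (adjusted p 0.113, 6 of 12 rose, such as FASLG at 3.88 ± 0.90 and GZMK at 2.48 ± 0.66), checkpoint receptors (0.180, 5 rose and 1 fell of 16, TIGIT at 3.73 ± 0.78), proliferation (0.226), T cell markers (0.385, 1 rose and 3 fell of 13), interferon response (0.769), MHC class II (0.788), the ILC3 program (0.812, 1 rose), myeloid markers (0.840, 2 rose) and the ILC2 program (0.924). In the ILC2 program IL1RL1 (3.05 ± 1.05) and ICOS (2.25 ± 0.85) rose while PTGDR2 (-3.65 ± 1.28) and BCL11B (-1.97 ± 0.69) fell, and its test was down while its median was up.

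**Figure D4:**
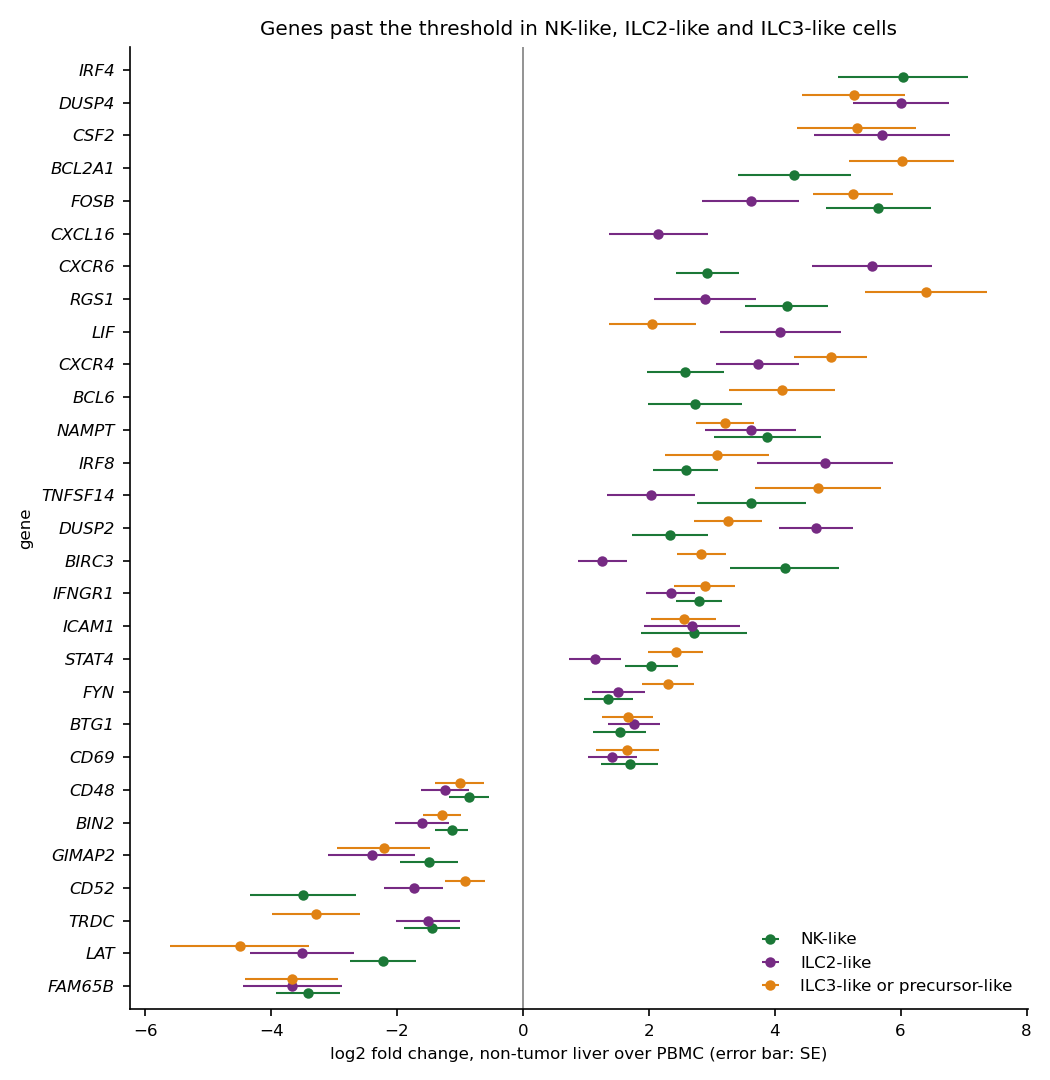
Log2 fold change, non-tumor liver over PBMC, of 29 genes among those that passed in the same direction in NK-like, ILC2-like and ILC3-like or precursor-like cells; bars are standard errors, and values with at most 3 counts in a group are not drawn. RGS1 lay at 4.19, 2.89 and 6.4 and FAM65B at -3.41, -3.66 and -3.67.

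The contrast of liver and blood was then made within classes. RNA of other cells in a library can still enter these sums, so the share of cells with a molecule was set beside that of B-like cells of the same libraries (of T-like cells for CD79A and CD79B), a check chosen after seeing the data. Background RNA is called not excluded unless the share was higher in each library, by more than the larger SD on average. B-like cells may also express a gene themselves, and RNA of the other ILC-like and NK-like cells is not tested by this. In NK-like cells (5 against 4 libraries) 73 of 196 genes passed, 51 higher in liver and 22 in PBMC, and 37 with at least 50 cells per library, which leaves 2 PBMC libraries. In ILC2-like cells (3 against 4) 55 of 176 passed, 38 and 17, and in ILC3-like or precursor-like cells (3 against 4) 91 of 190 passed, 65 and 26. DESeq2 gave 87, 65 and 100. Clusters of a class differ by site, so genes that led a cluster are not independent of the naming. Without such leading genes 59, 50 and 76 genes remained. Of 145 genes tested in all 3 classes, 23 rose in each and 8 fell in each. If the classes were independent, 2.55 and 0.315 would be expected, but they come from the same libraries. Shared rises included FOSB (5.65 ± 0.83, 3.62 ± 0.77 and 5.24 ± 0.64 in NK-like, ILC2-like and ILC3-like cells), the chemokine receptor CXCR4 (2.58 ± 0.61, 3.73 ± 0.66 and 4.89 ± 0.58), IFNGR1 (2.80 ± 0.37, 2.35 ± 0.39 and 2.89 ± 0.48) and CD69 (1.69 ± 0.45, 1.42 ± 0.39 and 1.66 ± 0.50). Shared falls included FAM65B (-3.41 ± 0.50, -3.66 ± 0.78 and -3.67 ± 0.73) and LAT (-2.23 ± 0.53, -3.51 ± 0.83 and -4.50 ± 1.1).

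In NK-like cells RGS1, VEGFA and LIF were among the genes higher in non-tumor liver, and CX3CR1 and FCGR3A among those higher in PBMC. Rises were largest in IRF4 (6.03 ± 1.03), IFNG (5.91 ± 1.60), FOSB, BCL2A1 (4.31 ± 0.89), RGS1 (4.19 ± 0.65) and BIRC3 (4.16 ± 0.87), all higher in 5 of 5 libraries. Ratios were 56.9 for VEGFA (10.2 to 2249), 137 for LIF (24.6 to 5425), 13.7 for DUSP4 (3.78 to 113), 26.4 for CXCL16 (4.72 to 1043) and 38.9 for CSF2 (13.3 to 189), and TYMS was at least 5.58-fold higher. These ratios pool the counts of a group, and 6873 of the 8862 non-tumor NK-like cells came from non-tumor B. Falls, each in 5 of 5 libraries, were in CX3CR1 (-6.17 ± 1.19), CD52 (-3.49 ± 0.84), FAM65B, FCGR3A (-2.94 ± 0.82), KLRG1 (-2.43 ± 0.85), LAT, TRAC (-2.22 ± 0.58), GZMH (-2.05 ± 0.75), TSPAN32 (-1.78 ± 0.42) and GIMAP2 (-1.49 ± 0.46). In the 5 non-tumor libraries IFNG was seen in 22.7% ± 14.9 of NK-like and 2.07% ± 3.24 of B-like cells, RGS1 in 63.2% ± 8.65 and 30.8% ± 14.4, VEGFA in 15.4% ± 8.19 and 2.52% ± 2.80 and LIF in 9.98% ± 7.78 and 0.0885% ± 0.198. By the rule above background RNA is not excluded for the other 8 rises named: IRF4, FOSB, BCL2A1, BIRC3, DUSP4, CXCL16, CSF2 and TYMS. In the 4 PBMC libraries CX3CR1 was seen in 37.6% ± 21.3 and 0.0683% ± 0.0798 and FCGR3A in 39.8% ± 28.3 and 0.346% ± 0.514, and background RNA is not excluded for TRAC, CD52 and FAM65B. IFNG, DUSP4, CX3CR1, FCGR3A and GZMH are leading genes of NK-like clusters. With at least 50 cells per library IFNG, DUSP4, CSF2, TYMS, KLRG1, LAT, TRAC, GZMH and GIMAP2 did not pass (adjusted p up to 0.109). Without the filter on low counts 21 of the 24 genes picked by the rule passed in NK-like cells. In ILC2-like cells 22 of 24 did, and in ILC3-like or precursor-like cells 23 of 24. Left out singly, some libraries removed calls: TYMS without PBMC B (adjusted p 0.0557), DUSP4 without PBMC B or non-tumor C (up to 0.0596) and GIMAP2 without PBMC B, C or D (up to 0.0538). It was lost for CSF2 without PBMC B, C or D or non-tumor B or C (up to 0.0903), GZMH without PBMC B, C or F or non-tumor B, C or D (up to 0.0896), and KLRG1 without PBMC B or C or non-tumor C, D, E or F (up to 0.138).

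In ILC2-like cells DUSP4, CSF2 and CXCR6 were among the genes higher in non-tumor liver. CCL5 (6.41 ± 1.22), DUSP4 (6.01 ± 0.76), CSF2 (5.71 ± 1.08), CXCR6 (5.54 ± 0.95) and IL2RB (4.91 ± 0.63) rose, each in 3 of 3 libraries. CCL4 was at least 57.7-fold, EGR3 55-fold, CXCL2 41.2-fold and IFNG 8.94-fold higher. Ratios were 361 for VEGFA (63.9 to 14334), 151 for CXCL8 (26.2 to 6026) and 53.6 for IRF4 (8.81 to 2198). FAM65B, LAT, GIMAP5 (-2.84 ± 0.89), GIMAP2 (-2.40 ± 0.69), IFITM2 (-1.79 ± 0.35), CD52 (-1.73 ± 0.47), TIAF1 (-1.62 ± 0.58), BIN2 (-1.61 ± 0.43) and TRIB2 (-1.55 ± 0.41) fell. CD79B was at least 8.57-fold lower, and LGALS9 had a ratio of 14.7 (4.88 to 72.7) in favour of PBMC. In the 3 non-tumor libraries CSF2 was seen in 31.0% ± 13.8 of ILC2-like and 0% of B-like cells, CXCR6 in 41.6% ± 5.59 and 0%, IL2RB in 76.2% ± 9.73 and 7.88% ± 7.45 and DUSP4 in 46.1% ± 17.2 and 11.1% ± 2.25. Background RNA is not excluded for VEGFA (21.8% ± 24 and 3.46% ± 3.34), CCL5, CCL4, EGR3, CXCL2, IFNG, CXCL8 and IRF4, nor in PBMC for FAM65B, CD52, TIAF1 and LGALS9, or for CD79B, which was seen in 9.71% ± 4.48 of ILC2-like and 8.59% ± 5.89 of T-like cells. LAT is a leading gene of cluster 7. With the donor replicate block GIMAP5 (adjusted p 0.0754) and TIAF1 (0.0590) did not pass. Calls were also lost for CD52 without non-tumor D (adjusted p 0.0531), CXCL2 and CXCL8 without non-tumor C (0.136 and 0.0866), LGALS9 without any 1 non-tumor library (up to 0.116) and GIMAP5 without non-tumor C or D or PBMC E (up to 0.0830). It was lost for TIAF1 without non-tumor B or D or PBMC B, E or F (up to 0.149), and for IFNG without non-tumor B or D or any 1 PBMC library (up to 0.227).

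In ILC3-like or precursor-like cells VEGFA, CCL20 and CXCL2 were among the genes higher in non-tumor liver. In the 3 non-tumor libraries VEGFA was seen in 58.4% ± 27.7 of these cells and 3.46% ± 3.34 of B-like cells, CCL20 in 26.3% ± 26 and 0% and CXCL2 in 9.83% ± 3.58 and 1.23% ± 2.14. Background RNA is argued against for RGS1 too, but not for CXCL8, TYMS, CXCL16, QPCT, IRF4, TGFBI, FOSL1 and BCL2A1. VEGFA had no count in PBMC cells of the class and was at least 753-fold higher. On the same floor CXCL8 was at least 161-fold, CXCL2 54.9-fold, TYMS 23.5-fold, CXCL16 20.7-fold and QPCT 11.9-fold higher. Ratios were 596 for CCL20 (107 to 23552), 535 for IRF4 (95.8 to 21138), 120 for TGFBI (21.4 to 4767) and 25.3 for FOSL1 (4.38 to 1013). RGS1 (6.4 ± 0.97) and BCL2A1 (6.02 ± 0.83) rose in 3 of 3 libraries. LAT, ZNF683 (-4.24 ± 1.32), GIMAP5 (-3.78 ± 0.78), FAM65B, CD79B (-3.62 ± 1.3), TRDC (-3.28 ± 0.70), LGALS9 (-3.08 ± 1.14), TSPAN32 (-2.86 ± 0.48), ITGAX (-2.80 ± 0.90), CD79A (-2.74 ± 0.66) and LGALS1 (-2.57 ± 0.68) fell. VEGFA, CCL20, FAM65B, TSPAN32 and ITGAX are leading genes of the 2 clusters of the class. In PBMC, CD79A was seen in 19.2% ± 1.82 of these cells and 2.52% ± 2.38 of T-like cells, and CD79B in 8.33% ± 5.33 and 8.59% ± 5.89, so background RNA is not excluded for CD79B, nor for FAM65B, LGALS9 and ZNF683. ZNF683 did not pass with the donor replicate block (adjusted p 0.0735). Calls were lost for CD79B (up to an adjusted p of 0.0932) and LGALS9 (up to 0.0930) without non-tumor B or C or PBMC D.

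Tumor and PBMC were compared to ask how sorted cells of the tumor differ from those of blood. Of 340 genes 93 passed, with FOSB and RGS1 among those higher in tumor and TCL1A and CD79B among those higher in blood. B-like cells made up 9.39% ± 10.9 (n = 6) of sorted tumor cells and 50% ± 17.7 (n = 5) of sorted PBMC, with an exact permutation p of 0.00216, the smallest this design can give, and an adjusted p of 0.0909. Without tumor E the tumor mean was 6.12%. NK-like cells made up 20.2% ± 13.2 and 6.59% ± 3.93 (exact permutation p 0.0563).

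Over all cells, 93 of 340 genes passed between tumor and PBMC, 62 higher in tumor and 31 in PBMC, and DESeq2 gave 125. The largest rises were CXCL2 at 7.75 ± 1.46 (2375 against 8.75 CPM), TPSAB1 at 7.71 ± 2.81, C1QA at 7.62 ± 2.14, CCL20 at 7.10 ± 1.38, IFNG at 6.52 ± 1.86 and VEGFA at 6.51 ± 1.07. Ratios of counts were 8807 for CHI3L1 (1580 to 347858), 2482 for SPP1 (687 to 20498), 1749 for C1QB (598 to 8483), 434 for CXCL3 (120 to 3583), 223 for CXCL9 (61.7 to 1847) and 133 for CCL22 (36.7 to 1103). Each was above the PBMC mean in 6 of 6 tumor libraries except CHI3L1 (5), TPSAB1 (4) and CXCL9 (3). CXCL2, CHI3L1 and SPP1 are leading genes of the unnamed cluster 4, C1QA and C1QB of the myeloid-like cluster 16, CCL22 of cluster 10 and CCL20 of cluster 3. Tumor A supplied 94.3% of the cells of cluster 4 and 77.9% of those of cluster 16. Myeloid-like cells made up 6.72% of tumor and 5.82% of PBMC cells on average, and 3.24% without PBMC C. Falls were in B cell genes TCL1A (-7.12 ± 1.32), IGHM_membrane (-5.12 ± 1.26), CD79B (-4.92 ± 0.94), IGHD_membrane (-4.79 ± 1.33), PAX5 (-4.38 ± 1.14), FAM129C (-4.21 ± 1.12), CD24 (-4.10 ± 0.97), FCER2 (-4.00 ± 1.08) and POU2AF1 (-3.95 ± 1.0), in IGHA1_secreted (-6.34 ± 2.00) and TNFRSF17 (-4.14 ± 1.46), and in the monocyte gene S100A12 (-6.60 ± 1.90). All 12 fell in 6 of 6 tumor libraries. With the donor replicate block TPSAB1 (adjusted p 0.0986), CXCL9 (0.120) and S100A12 (0.0589) did not pass. Single libraries mattered for IGHA1_secreted, lost without PBMC E (adjusted p 0.126), TPSAB1 without any 1 PBMC library (up to 0.0939), and TNFRSF17 without any 1 tumor library or PBMC C, E or F (up to 0.153). Without tumor A only 22 of the 24 genes picked by the rule could still be tested, and 21 of these passed. The same counts held without tumor F.

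Of the 16 lists, 6 passed between tumor and PBMC, none of them with an estimated correlation (adjusted p = 0.381 to 0.739). Immediate early genes rose (adjusted p 2.37e-04; 5 of 10 rose, 6 adjusted over the list alone), with FOSB at 4.19 ± 0.57 and DUSP4 at 6.10 ± 0.89. Residency rose (0.00114; 3 of 11 rose, 3 alone), with RGS1 at 5.13 ± 0.78 and CXCR6 at 4.52 ± 0.71. Circulation fell (0.00111; 3 of 8 fell, 3 alone), with CX3CR1 at -3.74 ± 1.04 and CD27 at -2.73 ± 0.92. B and plasma cell markers fell (0.00152; 12 of 20 fell, 15 alone). Cytokines rose (0.0202; 11 of 19 rose, 13 alone), with IL13 at 6.31 ± 1.80, and the ILC1 program rose (0.0260; 3 of 10 rose, 3 alone), with IL12RB2 at 2.78 ± 0.67. Leaving out 1 library left 4 to 7. Proliferation (adjusted p 0.0795, 4 of 8 rose, TOP2A at 3.27 ± 1.00) and the ILC2 program (0.297, 5 of 10 rose, IL1RL1 at 5.51 ± 1.1 and ICOS at 3.61 ± 0.88) did not pass, nor did NK receptors (0.809) or the other lists (0.511 to 0.924). With the donor replicate block the ILC2 program (0.0216) and proliferation (0.0431) passed, both up.

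Margin and PBMC were compared with the same question. RGS1 and DUSP4 were among the genes higher in margin and TCL1A and CD79B among those higher in blood. B-like cells made up 5.98% ± 6.99 (n = 5) of sorted margin cells (mean 3.10% without margin F), with an exact permutation p of 0.00794 against PBMC, the smallest possible, and an adjusted p of 0.167. Over all cells 88 of 340 genes passed, 52 higher in margin and 36 in PBMC. DESeq2 gave 129 and version 1.3 libraries alone 51. Rises were largest in CCL20 (6.96 ± 1.38), VEGFA (6.83 ± 1.09), DUSP4 (6.20 ± 0.90), IFNG (6.12 ± 1.85), CXCL2 (6.09 ± 1.37) and RGS1 (5.71 ± 0.81, 18966 against 361 CPM). MMP9 was at least 28.8-fold higher. Ratios were 1601 for CHI3L1 (287 to 63287), 695 for SPP1 (192 to 5748), 271 for CCL22 (74.8 to 2247), 158 for C1QB (53.9 to 771) and 85.5 for CXCL3 (23.3 to 711). Falls, each in 5 of 5 libraries, were in TCL1A (-7.11 ± 1.43), IGHM_membrane (-5.85 ± 1.41), PAX5 (-5.22 ± 1.28), VPREB3 (-5.11 ± 1.3), CD79B (-5.03 ± 1.03), IGHD_membrane (-4.85 ± 1.44), FCER2 (-4.63 ± 1.20), FAM129C (-4.61 ± 1.23) and CD22 (-4.42 ± 1.36). The monocyte genes S100A9 (-6.45 ± 2.08), S100A12 (-5.87 ± 1.99) and FCN1 (-5.10 ± 1.78) fell too. Among version 1.3 libraries 10 of the named genes did not pass (adjusted p up to 0.156): C1QB, IFNG, S100A9, S100A12, FCN1, PAX5, IGHD_membrane, FCER2, FAM129C and CD22. The call was lost for IFNG without PBMC F (adjusted p 0.0511), CD22 without margin C or PBMC F (up to 0.0552), CHI3L1 without margin A or PBMC B (up to 0.119) and C1QB without margin A or PBMC B, C, D or E (up to 0.0859). It was lost for S100A9 (up to 0.0641), S100A12 (up to 0.0859) and FCN1 (up to 0.0926) without PBMC B or C or margin B, C or E, for S100A12 and FCN1 also without margin F, and for FCN1 also without margin A.

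Of the 16 lists, 6 passed between margin and PBMC, none of them with an estimated correlation (adjusted p = 0.381 to 0.739). Immediate early genes rose (adjusted p 2.69e-04; 4 of 10 rose, 6 adjusted over the list alone), with FOSB at 4.30 ± 0.58. Residency rose (0.00114; 3 of 11), circulation fell (0.00172; 4 of 8, CX3CR1 at -3.32 ± 1.08 and ITGAM at -1.77 ± 0.64), B and plasma cell markers fell (0.00701; 9 of 20, 10 alone), cytokines rose (0.0314; 9 of 19, 11 alone, CSF2 at 5.11 ± 1.14) and the ILC1 program rose (0.0260; 3 of 10, STAT4 at 2.37 ± 0.48). Leaving out 1 library left 4 to 7. The other lists had adjusted p of 0.113 to 0.808, and in the ILC2 program IL1RL1 (4.96 ± 1.09), ICOS (3.75 ± 0.90), IL13 (5.07 ± 1.73) and CCR4 (3.12 ± 1.12) rose. With the donor replicate block the ILC2 program (adjusted p 0.0104), the ILC3 program (0.0268) and checkpoint receptors (0.0144) passed as higher and interferon response (0.0412) as lower.

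The 10x tumor library of donor G is a single library without replicates, so its values carry exact 95% Clopper-Pearson intervals and no test. Of 3800 barcodes, 3799 had at least 200 genes, with 7011570 molecules in total and medians of 1191 molecules and 680 genes per cell. Of these cells, 11.6% (10.6% to 12.7%) were ILC3-like or precursor-like (clusters led by KRT86, IL7R and IL4I1, and by DLL1 and KIT). NK-like cells made up 7.74% (6.91% to 8.63%), with GZMK and XCL2 leading 1 cluster and GNLY and FCGR3A the other, T-like cells 5.26% (4.58% to 6.02%) and myeloid-like cells 0.921% (0.643% to 1.28%). Unnamed clusters held 74.5% (73.0% to 75.8%). Cluster 2 among them was led by BACH2, SLAMF1, RORA, KIT and PPARG, and cluster 4, with 448 cells (11.8%), by heat shock genes such as HSPA6, HSPH1 and HSPA1B. No cluster was named ILC2-like at the main resolution, but 9.48% of cells were so named at resolution 2, where ILC3-like or precursor-like cells fell to 4.58%.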

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

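Of 209 groups of values looked at, 24 held a library apart from the rest, where chance alone marks about 1 in 20, or about 10. For the patterns weighed here, the tests of doublets in the unnamed cluster and of depth in the immediate early pattern were chosen only after the result was seen, as were the counts over other splits. The tests of handling and of the NK-like share rest on lists within class, which were also chosen after seeing the data. So were the alternatives behind the tests of pipeline version and of the libraries in doubt.

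Tumor library A stood apart in its 4408 cells (others up to 1249), its total of 1218860 counts (others up to 451685) and its unnamed cells, at 57.7% (others up to 2.48%). Tumor D had 67.3% ILC2-like cells (others up to 19.8%) and tumor F 45.9% T-like cells (others up to 10.3%). Among margin libraries, margin E stood apart in its total of 1325811 counts (others up to 321750), in plasma cells at 24.4% (others up to 3.99%) and in IL12RB2 at 69.2 CPM (others from 255.5). Margin F had 21.2% myeloid-like cells (others up to 4.65%) and margin A 18.7% unnamed cells (others up to 1.3%). Margin B was low in MMP9, at 8.66 CPM (others from 46.1), and had 0 CXCL9 counts (others from 46.1 CPM).

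Among non-tumor libraries, non-tumor B had 7452 cells (others up to 1914) and 27345 CPM of CCL4 (others up to 4350). Non-tumor C had 6.06% ILC2-like cells (others up to 1.88%), 39.4% ILC3-like or precursor-like cells (others up to 8.19%) and 511.6 CPM of DPP4 (others up to 66.2). Non-tumor E had 70.8% B-like cells (others up to 18.5%). Non-tumor F had 39.2% myeloid-like cells (others up to 8.52%), 1059 CPM of LIPA (others up to 549.7) and 1053 CPM of TPSAB1 (others up to 0.904). PBMC B had 496476 counts (others up to 284477). PBMC F had 11434 CPM of TCL1A (others up to 4449) and 60184 CPM of IGHM_membrane (others up to 23253). In data that no main test used, the non-tumor library deposited as reads had 73.9% NK-like cells, inside the range of the other non-tumor libraries (10.7% to 92.2%), so it does not stand out.

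The first pattern weighed is the unnamed cluster 4, with 2560 cells, 94.3% of them from tumor library A, led by MGST1, CHI3L1, AQP9, FN1 and F5. Myeloid cells are argued against, since 12 of 13 measured myeloid markers had at most 8.27% of their level in myeloid-like clusters, with CD14 at 52.2% the exception. The same markers named the myeloid-like clusters, so a lower level than there follows in part from the naming. Free RNA from other cells would give the leading genes similar levels in lymphocytes of the same library, where their median was 1.99% of that in the cluster. This goes against free RNA. The genes were chosen for being higher in the cluster than in other cells, however, so the low value follows in part from that choice. Doublets are argued against by the molecules per cell, with a median at 0.830 of that of the other cells of tumor A. Tumor or liver parenchymal cells that passed the sort remain a candidate source, but 0 of 15 hepatocyte and stromal markers are on the panel, so this was not tested.

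The second pattern is the immediate early list, higher in liver than in blood. If handling of tissue during cell isolation were behind it, classes unrelated to ILCs would show it too. In B-like cells, non-tumor against PBMC, its median log2 change was 2.74 with 10 of 10 genes higher, a result that goes with handling. It argues against a state of NK-like and ILC-like cells alone only if their RNA did not enter the B-like sums, which was not tested. The B-like cells also differ by site: cluster 11 held 87.8% of them in non-tumor liver and cluster 6 held 81.5% in PBMC. A difference between these clusters cannot be told apart from handling here. Depth is argued against by the molecules per cell, whose ratio of group means was 1.03. Life in liver tissue itself, with its antigens and cytokines, could act on all classes alike and was not tested.

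The third pattern is the NK receptor list, lower in tumor than in non-tumor liver. A lower share of NK-like cells goes with the values: within NK-like cells the median log2 change was -0.16 against -1.57 over all cells. The libraries in doubt are not excluded: without both the median was -1.36 (adjusted p 0.0445), but margin E is in neither group, and without tumor A alone the median was -1.44 (adjusted p 0.0622). Pipeline version cannot be told apart from donor, because tumor A is the only molecule library of these 2 groups made with the older version, and among libraries of the newer version the median was -1.47 (adjusted p 0.0897). A change in the tumor that lowers NK-like cells, or a sort that recovers fewer of them from tumor, may stand behind the share, and neither was tested.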

How the results depend on the processing

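The alternatives with high doublet scores, immunoglobulin amplicons, libraries of the older pipeline version or the 2 libraries in doubt left out, and shares among NK-like and ILC-like cells alone, were chosen after seeing the data. Over counts and shares, 255 of 283 values under an alternative were labelled the same, 5 weaker, 5 stronger and 18 moved. With 1 library left out, 286 of 294 were the same. A count of calls was the same if it stayed at 0 or within 1.5 times, and its direction was not compared. All share tests and most tests between tissue sites had 0 calls. Much of this agreement is therefore 0 repeated, which does not show that a result is robust. No class share passed in any comparison under any alternative or library left out. Over all classes, a single share cannot pass even at the smallest exact permutation p of 0.00216 (adjusted p 0.0909). The 0 calls over all classes therefore say little. Paired sign-flip permutation tests within donors cannot give a p under 0.0625 with 5 pairs or 0.125 with 4, so their 0 calls decide nothing. Named genes were compared by their direction and side of the threshold. For these 1836 of 1891 values under alternatives were the same, 49 weaker, 1 stronger and 5 reversed. With 1 library left out, 1702 of 1828 were the same, 118 weaker, 1 stronger and 7 reversed. Where not stated, the cause was not tested.

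Over all cells, non-tumor against PBMC gave 54 genes with total counts in place of TMM and 67 with only the 2 groups compared, where fewer samples set the spread. Margin against PBMC gave 51 among version 1.3 libraries, which drops 2 margin libraries. NK-like cells, non-tumor against PBMC, gave 37 with at least 50 cells per library, which leaves 2 PBMC libraries. Margin against non-tumor gave 1 gene, CHI3L1, without the 2 doubted libraries. With the donor as a replicate block, tumor against non-tumor gave 1 gene (IGHA1_secreted, down), and lists numbered 2 for tumor against non-tumor, 2 for margin against non-tumor and 10 for margin against PBMC. Beside these and the lists and genes given with their comparisons, the block changed no call of a named gene or list. Leaving out 1 library gave 0 to 1 genes for tumor against non-tumor over all cells (DPP4 without non-tumor C), and 0 to 1 in ILC2-like cells both for tumor and for margin against non-tumor (PTGDR2 without non-tumor C). Against PBMC the counts ran from 75 to 126 for non-tumor, 67 to 98 for tumor and 61 to 86 for margin, and within NK-like, ILC2-like and ILC3-like or precursor-like cells from 51 to 75, 42 to 53 and 76 to 94.

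Camera with an estimated correlation, which compares a list with other genes, called 0 lists in tumor against non-tumor and in non-tumor, tumor and margin against PBMC. With the preset correlation it called 2 for tumor against non-tumor, 2 for margin against non-tumor, 3 for tumor against margin, 4 for non-tumor against PBMC, and 3 each for tumor and margin against PBMC. Among version 1.3 libraries tumor against non-tumor had 0 lists, and with 1 library left out 0 to 2.

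Single genes that reversed had not passed in the main test. Without the 2 doubted libraries, log2 changes were 0.28 for TNFRSF17 (tumor against margin), and for IGKC -0.52 (ILC2-like, margin against non-tumor), 2.08 (ILC2-like, tumor against margin) and 0.46 (ILC3-like, tumor against margin). With the replicate block IGKC was at -0.0542 (ILC2-like, margin against non-tumor). With 1 library left out, tumor against margin ran from -0.33 to 3.78 for ZNF683, -3.93 to 0.19 for TNFRSF17, -1.12 to 5.13 for IGHG2_secreted in NK-like cells, and for IGKC from -4.60 to 1.90 in ILC2-like and -1.90 to 0.44 in ILC3-like cells. Margin against non-tumor ran from -0.62 to 6.30 for IGKC (ILC2-like) and -2.83 to 0.72 for NKG7 (ILC3-like).

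In the 10x library, at least 500 genes per cell gave 8.88% NK-like and 71.8% unnamed cells. Resolution 0.5 gave 8.53% ILC3-like and 78.2% unnamed cells, leaving out the 2 marked doublets left 7.74% NK-like and 11.6% ILC3-like cells, and resolution 2 gave 9.48% ILC2-like, 4.58% ILC3-like, 5.03% hepatocyte-like and 66.8% unnamed cells.

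Other scalings shifted the median log2 change of all genes by over 0.1 in these cases: total counts by 0.12 for tumor and 0.14 for margin against non-tumor and by 0.14 for tumor against PBMC, and DESeq2 size factors by 0.19 for margin against non-tumor and, within class, by -0.18 (NK-like) and -0.21 (ILC3-like) for non-tumor against PBMC and by 0.10 (ILC3-like) for margin against non-tumor. Not run were protein tags (0 tag columns), doublets by the caller (71 cells marked), and ILC2-like cells with at least 50 cells per library in comparisons with non-tumor liver, where 1 library remained. Most small changes would be missed: in simulated data at most 8.60% of 2-fold and 41.5% of 4-fold changes were recovered over all cells and at most 27.4% and 80.4% within classes. Depth was not varied, so its part in this is not known.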

Other observations

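The list tests within class and the counts over other splits reported here were chosen only after the main results were seen.

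Other splits of the same libraries into groups of the same sizes were tested the same way, 100 of them where more exist. For non-tumor liver against PBMC, 1 of 100 splits, the real one, gave as many genes over all cells (112, highest other 12) and lists (7, highest other 3). For tumor against PBMC this was also 1 of 100 for genes (93, highest other 39) and lists (6, highest other 5), and for margin against PBMC 1 of 100 for genes (88, highest other 5) and lists (6, highest other 1). Within classes, non-tumor against PBMC, it was 1 of 100 in NK-like cells (73, highest other 33), 1 of 35 in ILC2-like cells (55, highest other 27) and 1 of 35 in ILC3-like or precursor-like cells (91, highest other 60). No other split reached these counts.

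Donor numbers pair the libraries, so splits that part as many pairs of the same donor as the real one were tested too. The other splits of this kind swap the site labels within donors, and libraries without a partner from the same donor can also change sides. Those above can also put libraries of the same donor on the same side. Against PBMC only the real split gave its count. For genes this was 1 of 32 for tumor (highest other 2), 1 of 16 for non-tumor liver (highest other 8) and 1 of 16 for margin (highest other 0), and for lists the highest others were 3, 2 and 0. Within classes, non-tumor against PBMC, the highest others were 27 (NK-like), 25 (ILC2-like) and 60 (ILC3-like or precursor-like), over 16, 12 and 12 splits. With 16 splits or fewer a share under 0.05 cannot be reached. The 1 list call for tumor against non-tumor liver was reached by 5 of 32 such splits.

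Between tissue sites most real counts are 0. Every split reaches a count of 0, so the shares for these say nothing about chance. With the donor as a replicate block the NK receptors (adjusted p 0.0169) and the ILC2 program (0.0180) passed for tumor against non-tumor liver, a fit that was not repeated over splits. For tumor against non-tumor liver, where the real split called 1 list, 34 of 100 splits, the real one included, called at least 1 list of any kind (highest other 7). Whether those splits called the NK receptor list itself was not counted. The counts of 0 genes were matched by 100 of 100 splits in each of the 3 tissue comparisons over all cells, where single splits called up to 49, 28 and 6 genes for tumor against non-tumor, margin against non-tumor and tumor against margin. A split calling 49 genes where the real one calls 0 points to a structure of these libraries, whose nature was not tested. Over the 32 splits that part all pairs, no split called a gene in this comparison. The 0 lists of margin against non-tumor and tumor against margin were matched by 100 of 100 (highest other 3 and 2). Within NK-like cells the 0 genes were matched by 100 of 100 splits in each tissue comparison (highest other 3, 1 and 6). In ILC2-like cells they were matched by 56 of 56, 56 of 56 and 100 of 100 (highest other 5, 1 and 4), and in ILC3-like or precursor-like cells by 84 of 84, 56 of 56 and 100 of 100 (highest other 4, 1 and 6).

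Lists were also tested within classes, with fry alone. Camera was not run there, so whether these calls would hold with an estimated correlation is not known. For non-tumor liver against PBMC, immediate early genes rose in NK-like cells (median log2 change 2.71, adjusted p 0.00407, 7 of 10 rose alone), in ILC2-like cells (1.23, 0.00219, 5 of 10), in ILC3-like or precursor-like cells (2.29, 0.00193, 7 of 10) and in B-like cells (2.74, 2.18e-04). The residency list went up in NK-like (0.0304, 3 of 9 rose alone), ILC2-like (3.87e-04, 3 of 7) and ILC3-like or precursor-like cells (0.00343, 4 of 7, and 1 fell). The circulation list went down in NK-like cells (0.00219, 3 of 7 fell alone). In ILC2-like cells its test was down (0.0417), but of 6 members 1 fell and 1 rose alone, so its members do not share a direction. The test of cytotoxic effectors was down in liver NK-like cells (0.0113, 3 of 12 fell and 1 rose alone). Interferon response, with 3 genes measured, was down in ILC2-like (0.00512, 1 fell alone) and ILC3-like or precursor-like cells (0.0365, 1 fell alone). The values in parentheses after a class are adjusted p. In T-like cells of tumor against PBMC, immediate early genes rose too (median 2.00, adjusted p 0.0150).

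The library of non-tumor liver A deposited as reads held 935 cells and 21310149 reads. By transfer of cluster names, 73.9% of its cells were NK-like, 7.49% ILC3-like or precursor-like, 7.06% T-like and 3.21% ILC2-like. With it added, 113 genes passed for non-tumor against PBMC over all cells.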
